A study of Brachypodium distachyon with 6 samples.

How the data were processed

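Messenger RNA from roots of Brachypodium distachyon line Bd21, a small temperate grass used as a model for cereals, was sequenced from 6 biological replicates. Per the labels' protocols, seedlings were grown for 7 days on a nitrogen-poor medium and treated plants were then soaked for 1 h in 50 µM 2,4-dichlorophenoxyacetic acid (2,4-D), a synthetic auxin. Roots were taken 7 days after the treatment, when treated roots carried nodule-like structures. The labels do not say whether the untreated plants were soaked in a solution without hormone. RNA was isolated separately from each of 3 untreated and 3 treated replicates, per the series' design text, and libraries were made with a strand-specific Illumina mRNA kit.

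The authors deposited one table of raw counts, with no normalization. Per the file headers, the counts were made with featureCounts 1.4.3 on annotation version 2.1 of the genome, with read pairs counted as fragments of 50 to 1000 bp, exons as features and transcripts, not genes, as the unit of summary. Per the submitters' processing notes, bcl2fastq 1.8.4, FastQC 0.11.3, Subread 1.4.3 and limma 3.28.7 were also used, with no model stated. The command in the header sets no strand option, so antisense and overlapping transcripts cannot be told apart in these counts. It also sets no option to count a fragment for more than 1 transcript. Of 8312 transcripts with no exonic base of their own, 8174 had 0 counts in all libraries. A fragment lying in exons that several transcripts share was thus generally left uncounted.

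This affects loci with more than 1 annotated transcript. The table held 42868 transcripts of 31694 loci, and 6060 loci (19.1%) had 2 or more transcripts. Their transcripts had a median of 3 bp of exon not shared with another transcript, against 1281 bp in loci with 1 transcript. They averaged 54.1 counts per locus and library, against 514 in loci with 1 transcript. Of their transcripts, 61.5% had 0 counts in all libraries, against 11.4% in loci with 1 transcript. Levels of such loci are therefore poorly measured here, and the results below concern mainly loci with a single annotated transcript.

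Transcript identifiers in the table carry no gene names. The gene table given as a reference describes assembly version 3.0, and 0 of the identifiers in the counts matched its identifiers, so no gene names, products or gene lists could be attached. Lists of auxin, hormone, cell wall, nodulin-related and control genes had been fixed before the data were examined, as patterns on product descriptions, and could not be tested. Coordinates are those of the deposited table (annotation version 2.1). Transcripts are named by a rule fixed before the data were examined: the 2 with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 CPM (counts per 1e6 counted fragments) and no overlap between the groups.

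Library totals ranged from 12528548 to 14146109 counts. A floor of 3 counts corresponded to 0.212 to 0.239 CPM in one library. A fold against a group at 0 counts used a floor of 3 counts over the whole group. Intervals and floors cover counting error only. Within each group, pairs of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 18.5 or more, so none was a repeat of another.

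The comparison used edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter by group (minimum count 10), robust dispersion estimates and the quasi-likelihood F test. Transcripts with a Benjamini-Hochberg adjusted p under 0.05 were called changed. CPM values are scaled by the TMM-adjusted library sizes, and log2 fold changes are 2,4-D over untreated. Standard errors were derived from the fold change and the F statistic. Of the transcripts, 20061 passed the filter and held 99.8% of all counts.

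The test was checked on counts simulated for this comparison from the observed means, dispersions and library sizes, with 50 transcripts changed at each of 4 fold sizes. At 19705 transcripts run, edgeR recovered 0% of 2-fold, 32% of 4-fold, 80% of 8-fold and 88% of 16-fold changes and made 4 false calls. DESeq2 recovered 10%, 54%, 94% and 94% on 20061 transcripts and made 65 false calls. In this simulation the design thus had little power for changes below 4-fold. Fewer transcripts were changed in it than were called in the data, which makes the Benjamini-Hochberg cutoff stricter. Recovery in the data may therefore differ.

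Alternatives fixed before the data were examined were DESeq2 size factors, library totals and upper-quartile scaling in the same fit, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, no low-count filter, a filter of 1 CPM in 3 libraries, a test against a fold change of 2, a replicate block, and leaving out each library. Summing counts per locus and removing a per-library trend with exon number were added after the data were seen.

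Neighbouring loci, exon classes and chromosomes were also examined, and these choices were made after the data were seen. Each tested locus on a chromosome was represented by its transcript with the smallest adjusted p, which gave 19489 loci. Pairs of directly neighbouring tested loci called in the same direction were counted and compared with 100000 random placements of the calls (one-sided permutation test). On simulated random placements, that test gave p under 0.05 in 4.80% of 2000 cases (7.50% of the first 200, after which the number was raised). Exon classes were compared with Fisher's exact test (two-sided) and, within strata of abundance and length, with a Mantel-Haenszel odds ratio. The spread of calls over the 5 chromosomes was tested by 100000 permutations and, for lower loci, by rotating all calls together along the genome by every possible step. A test of isoform usage in loci with several transcripts was also tried; it called no locus, and it is not reported because its power was not tested. These steps used Python 3.11, numpy, scipy and statsmodels.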

Results

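The study compared root transcripts of untreated Bd21 plants with those of plants treated with 2,4-D, whose roots contained nodule-like structures 7 days after the treatment. Each group had 3 libraries. Total counts averaged 13604149 ± 931507 (SD, n = 3) in untreated roots and 13394274 ± 391498 (SD, n = 3) in treated roots. Because p-values of the tests on single transcripts rest on 3 libraries per group, they measure the spread between these plants and libraries. Fisher and permutation p-values below take loci or transcripts as units and do not measure that spread.

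Treated roots differed from untreated roots in 437 of 20061 tested transcripts, of which 296 were higher and 141 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among the transcripts that passed, the median fold was 6.13 for higher and 4.61 for lower ones. The test recovered 0% of simulated 2-fold and 32% of simulated 4-fold changes, so these medians describe only changes large enough to be called. Of the changed transcripts, 112 rose and 30 fell by more than 8-fold. Transcripts that rose held 0.407% ± 0.0346 of all counts in untreated roots and 2.28% ± 0.162 in treated roots (SD, n = 3). Transcripts that fell went from 2.72% ± 0.105 to 0.661% ± 0.0952 (SD, n = 3). All 437 changed transcripts had no overlap between the groups, as had 27.4% of the tested transcripts, where chance gives 10%. Of the risen transcripts, 12 had at most 3 counts in each untreated library, and 6 of the fallen ones had at most 3 counts in each treated library.

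The calls changed widely when single libraries were left out. Each such fit also has less power than the fit with all libraries. All 6 leave out 1 library, so library number does not account for the differences between them. Within each group, the counts below rose with the Pearson r (log2 CPM) of the 2 libraries that remained. This r was 0.920, 0.940 and 0.955 without untreated replicates 2, 1 and 3. It was 0.905, 0.916 and 0.976 without 2,4-D replicates 1, 2 and 3. So few fits cannot tell such spread from dependence on the library left out. Without untreated replicate 2, edgeR called 0 transcripts (2714 at an unadjusted p under 0.05), voom called 0 and DESeq2 called 1191. Without 2,4-D replicate 1 the count was 19, without 2,4-D replicate 2 it was 82, without 2,4-D replicate 3 it was 256, and without untreated replicate 1 it was 72. Without untreated replicate 3 it was 370, of which 228 were among the 437. At an unadjusted edgeR p under 0.05, the fits other than that without untreated replicate 2 held 3038 to 4799 transcripts. With all libraries 3889 were under that p. In the 6 edgeR fits with one library left out, each of the 437 transcripts kept its direction. As none of them overlapped between the groups, this outcome was all but fixed in advance and shows no stability. With all libraries, the DESeq2 Wald test called 2286 transcripts, and a test against a fold change of 2 called 78.

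**Figure D1:**
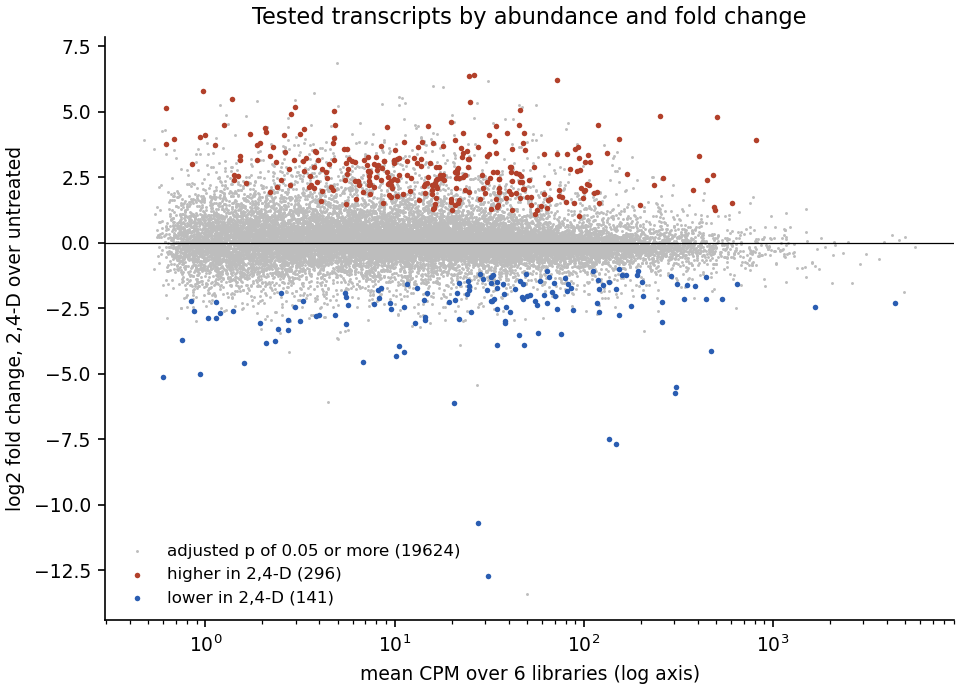
Each point is 1 of 20061 tested transcripts, with the mean CPM over 6 libraries on a log axis and the log2 fold change, 2,4-D over untreated, on the other axis. The 296 higher (red) and 141 lower (blue) transcripts lie across the range of abundance, and grey points did not pass the adjusted p.

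The 2 transcripts with the largest rise lie on chromosome 1. Bradi1g30950.1 (26507712 to 26509991, 3 exons) went from 0.593 CPM ± 0.652 to 52.0 CPM ± 24.7 (SD, n = 3 in each group; log2 fold change 6.39, SE 0.84, edgeR adjusted p = 0.0228). Bradi1g37410.1 (33401700 to 33402729, 2 exons) went from 0.588 CPM ± 0.464 to 48.6 CPM ± 43.6 (SD, n = 3 in each group; log2 fold change 6.38, SE 0.92, edgeR adjusted p = 0.0266). Its treated values were 28.0, 19.1 and 98.7 CPM, the last in 2,4-D replicate 3. Both transcripts are the only ones annotated at their loci.

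The 2 transcripts with the largest fall were near or at 0 counts in treated roots. Bradi4g43620.2 (chromosome 4, 47385017 to 47389440, 15 exons) had 62.1 CPM ± 60.2 in untreated roots (SD, n = 3) and 0 counts in every treated library. Against a floor of 3 counts over the treated group together it was 751-fold lower (edgeR adjusted p = 0.0410). The lower end of the two-sided 95% counting interval of the untreated over treated ratio was 609.9. Bradi1g64487.1 (chromosome 1, 63969440 to 63970755, 1 exon) had 2012 counts in the untreated libraries together and 1 in the treated ones. The ratio after scaling by library totals was 1981, with a 95% counting interval of 355 to 78282 (edgeR adjusted p = 0.0228). Their untreated levels spread widely. Bradi4g43620.2 had 130.5, 38.2 and 17.4 CPM in untreated replicates 1, 2 and 3, and Bradi1g64487.1 had 122.2, 29.9 and 12.9 CPM.

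Each of the 4 named transcripts lost its edgeR call without untreated replicate 2, with adjusted p of 0.118, 0.130, 0.142 and 0.0786 in the order named, and without 2,4-D replicate 1, with adjusted p of 0.0913, 0.0913, 0.121 and 0.136. Bradi1g30950.1 also lost it without untreated replicate 1 (edgeR adjusted p = 0.0591) or 2,4-D replicate 2 (0.0510). Bradi1g37410.1 lost it without untreated replicate 1 (edgeR adjusted p = 0.0754) or untreated replicate 3 (0.0658). Bradi4g43620.2 lost it without untreated replicate 1 (edgeR adjusted p = 0.0591), 2,4-D replicate 2 (0.0724) or 2,4-D replicate 3 (0.0759), and Bradi1g64487.1 without 2,4-D replicate 2 (0.0710) or 2,4-D replicate 3 (0.0656). Over all alternatives, adjusted p ran from 6.00e-16 to 0.118 for Bradi1g30950.1, from 2.01e-13 to 0.130 for Bradi1g37410.1, from 4.86e-15 to 0.142 for Bradi4g43620.2 and from 5.86e-12 to 0.136 for Bradi1g64487.1, the lowest from DESeq2 in each case. In the test against a fold change of 2, Bradi1g37410.1 (edgeR adjusted p = 0.0599) and Bradi4g43620.2 (0.0902) lost their calls. The direction was the same in every fit, which the naming rule of no overlap between the groups made all but certain. Sizes moved with single libraries. The log2 fold change of Bradi1g30950.1 was 7.74 without untreated replicate 3, and that of Bradi1g37410.1 was 7.20 without untreated replicate 1 and 5.34 without 2,4-D replicate 3. Against the floor of 3 counts, Bradi4g43620.2 was 367-fold lower without untreated replicate 1 and 493-fold lower without 2,4-D replicate 2. The ratio of Bradi1g64487.1 was 847 without untreated replicate 1 and 1300.03 without 2,4-D replicate 2. Without 2,4-D replicate 1, which held its only treated count, Bradi1g64487.1 was 441-fold lower against the floor.

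Some of the changed transcripts lay side by side. Among 19489 tested loci, 24 pairs of direct neighbours changed in the same direction, 16 pairs higher and 8 lower, where random placement of the calls gave 5.47 on average (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). In opposite directions there were 2 pairs. The number of same-direction pairs fell with the calls, to 4 without untreated replicate 1 (29.5 times the expected number), 1 without 2,4-D replicate 1 (71.9 times), 5 without 2,4-D replicate 2 (19.3 times) and 13 without 2,4-D replicate 3 (6.31 times), and without untreated replicate 2 there were no calls to place. The excess was smaller among the calls of the DESeq2 Wald test, with 212 pairs at 2.17 times the expected number. Allowing up to 2 other tested loci in between, 81 changed loci fell into 38 regions, of which 4 held 3 or more. Under this looser rule the excess over chance was also smaller, with 47 same-direction pairs up to 3 places apart, 2.88 times the expected number (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give), so part of the regions are expected by chance.

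In the region with the most changed loci, on chromosome 2 (38963135 to 38998239), 4 of 5 tested transcripts fell, each with 2 exons and on the same strand. Their log2 fold changes ranged from -3.51 to -2.28, and the 4 had 83.5 to 266.2 CPM on average in untreated roots and 7.31 to 39.9 CPM in treated roots. The transcript in between that did not pass the test had 13.4 CPM ± 11.3 and 2.96 CPM ± 2.62 (SD, n = 3; log2 fold change -2.17). On chromosome 4 (47365005 to 47389440), 3 of 3 tested transcripts fell, Bradi4g43620.2 among them. Its neighbour, with 3 exons, went from 597.1 CPM ± 324.0 to 13.3 CPM ± 1.39 (SD, n = 3; edgeR adjusted p = 0.00868), and a transcript with 17 exons went from 95.03 CPM ± 16.4 to 18.6 CPM ± 5.58 (SD, n = 3; edgeR adjusted p = 0.0167). A pair of 3-exon transcripts elsewhere on chromosome 4 (5488940 to 5498719) also fell, one from 593.3 CPM ± 212.5 to 11.3 CPM ± 4.39 and the other from 270.4 CPM ± 216.2 to 1.501 CPM ± 1.06 (SD, n = 3; edgeR adjusted p = 0.00889 and 0.0184).

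Higher transcripts formed the other regions with 3 changed loci. On chromosome 2 (56813133 to 56834099), 3 of 4 tested transcripts rose, with log2 fold changes of 2.24 to 3.64, and the fourth had a log2 fold change of 1.92 (edgeR adjusted p = 0.0614). On chromosome 1 (27510278 to 27598269), 3 of 5 tested transcripts rose, with log2 fold changes of 2.32 to 3.06. Between them lay 2 that did not pass the test, a transcript with 1 exon at 1.44 CPM ± 1.05 and 16.0 CPM ± 13.99 (SD, n = 3; edgeR adjusted p = 0.107) and one with 14 exons at 100.4 CPM ± 23.7 and 116.5 CPM ± 8.74 (SD, n = 3; edgeR adjusted p = 0.608).

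**Figure D2:**
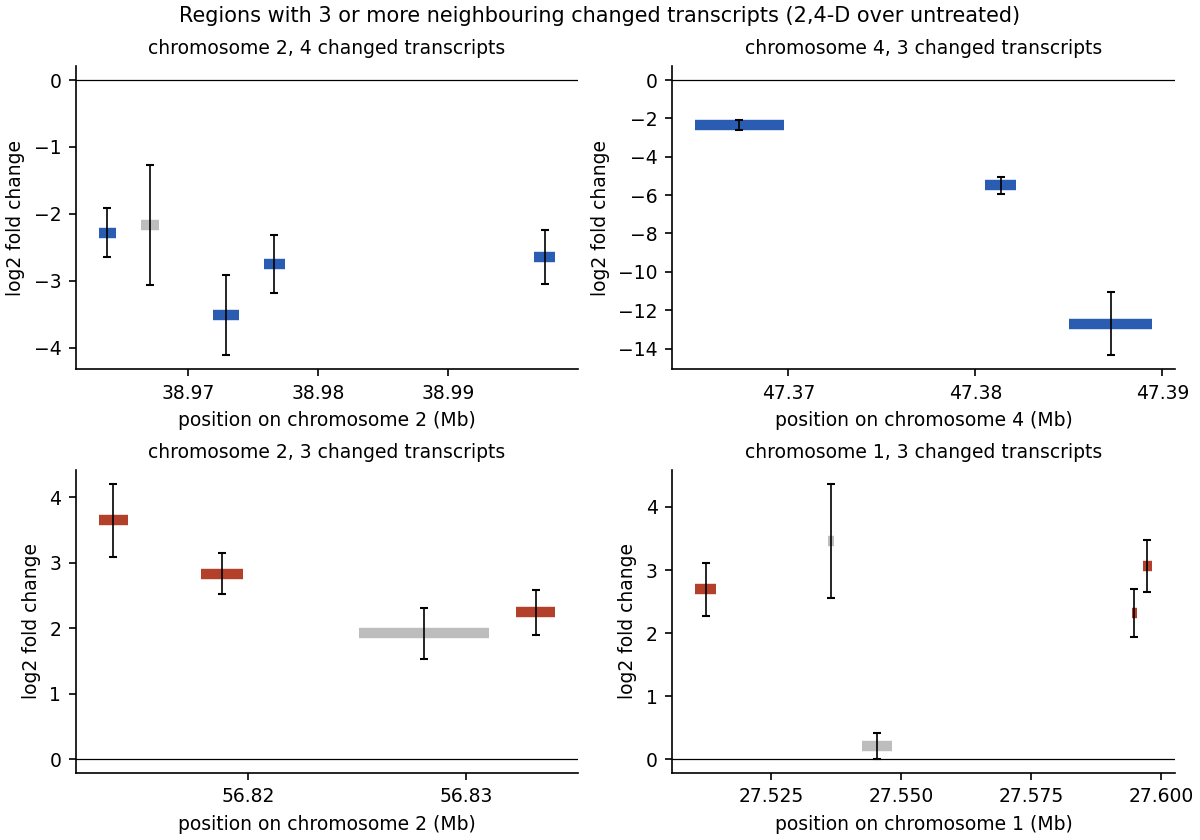
The 4 regions with 3 or more changed loci, with position in Mb (annotation version 2.1) on one axis and the log2 fold change, 2,4-D over untreated, on the other; each bar spans a tested transcript and error bars are SE. Blue transcripts fell, red ones rose and grey ones did not pass the adjusted p. The fall on chromosome 2 was shared by 4 of 5 tested transcripts. Bradi4g43620.2 had 0 counts in every treated library, so its plotted value of -12.7 was set by the fit and not by a measured treated level.

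Transcripts that rose had few exons. Of the 296 higher loci, 66.2% had 1 to 3 exons, against 48.8% of all tested loci (odds ratio 2.08, 95% interval 1.62 to 2.68, Fisher's exact p = 3.19e-09 adjusted over 2 tests). This test and its interval treat loci as independent and do not cover the spread between plants. The share of higher loci went from 2.33% of loci with 1 exon, through 1.92% with 2 to 3 and 1.18% with 4 to 9, to 0.596% with 10 or more. Lower loci had an odds ratio of 1.00 (95% interval 0.709 to 1.42, Fisher's exact p = 1.0). Within strata of abundance and length the odds ratio was 2.16 (95% interval 1.67 to 2.80) for higher and 1.35 (0.935 to 1.94) for lower loci, and the difference between higher and lower loci was not tested. The whole class of loci with 1 exon had a median log2 fold change of 0.37, against -0.06 in loci with 10 or more, so the shift was not limited to the called ones. Without untreated replicate 1 the odds ratio was 1.61 (Fisher's exact p = 0.116), and without 2,4-D replicate 1, on 16 higher transcripts, it was 4.46 (Fisher's exact p = 0.0116).

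**Figure D3:**
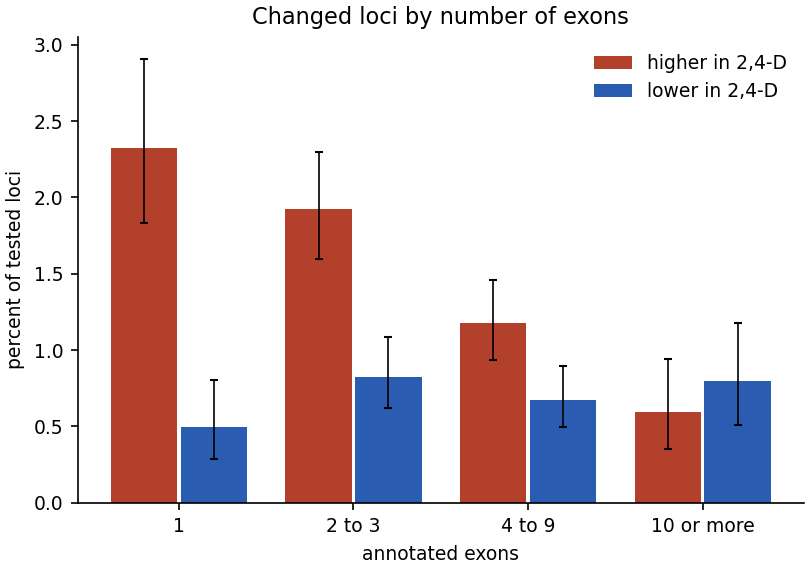
Percent of tested loci in each class of annotated exon number that were higher (red) or lower (blue) in 2,4-D, with exact 95% binomial intervals. Higher loci make up 2.33% of loci with 1 exon and 0.596% of those with 10 or more.

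Lower loci made up 1.18% of tested loci on chromosome 4 and 0.947% on chromosome 5, against 0.559% on chromosome 1, 0.558% on chromosome 2 and 0.644% on chromosome 3 (permutation p = 0.0106 adjusted over 2 tests, with calls placed independently). With the calls rotated together along the genome, the unadjusted p was 0.426. Rotation keeps the whole order of calls, longer dense stretches included, so it may miss a difference between chromosomes. With each region of neighbouring changed loci counted as 1 unit the unadjusted permutation p was 0.0213. With calls placed independently, the unadjusted permutation p was 0.0503 without untreated replicate 3, 0.536 without 2,4-D replicate 1, 0.184 without 2,4-D replicate 3 and 0.504 in the test against a fold change of 2. The difference between chromosomes thus depended on how the calls were placed, on single libraries and on the test. For higher loci the shares ran from 1.33% to 1.78% (permutation p = 0.433). Transcripts of loci with 2 or more annotated transcripts were changed in 31 of 3065 cases (1.01%), against 406 of 16996 (2.39%) in loci with 1 transcript (Fisher's exact p = 2.55e-07). Their median abundance was also lower, 2.84 CPM against 17.4 CPM.

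The treated libraries did not lie equally close to each other. On log2 CPM across transcripts, which are not independent replicates, 2,4-D replicates 1 and 2 had a Pearson r of 0.976, and 2,4-D replicate 3 had an r of 0.916 and 0.905 with them. Untreated libraries had an r of 0.920 to 0.955 with each other. Between the groups, r ran from 0.809 to 0.9277. 2,4-D replicate 2 had an r of 0.9245, 0.9264 and 0.9277 with untreated replicates 1, 2 and 3, each above its r with 2,4-D replicate 3. For 2,4-D replicate 1 this held for untreated replicate 1 (0.9187) but not for untreated replicates 2 and 3 (0.9103 and 0.9106). Whole profiles thus did not separate the libraries cleanly by treatment. Of the 296 higher transcripts, the highest treated value was in 2,4-D replicate 3 for 149, in replicate 1 for 118 and in replicate 2 for 29. Of the 141 lower ones, the lowest was in 2,4-D replicate 3 for 83, in replicate 2 for 32 and in replicate 1 for 26.

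**Figure D4:**
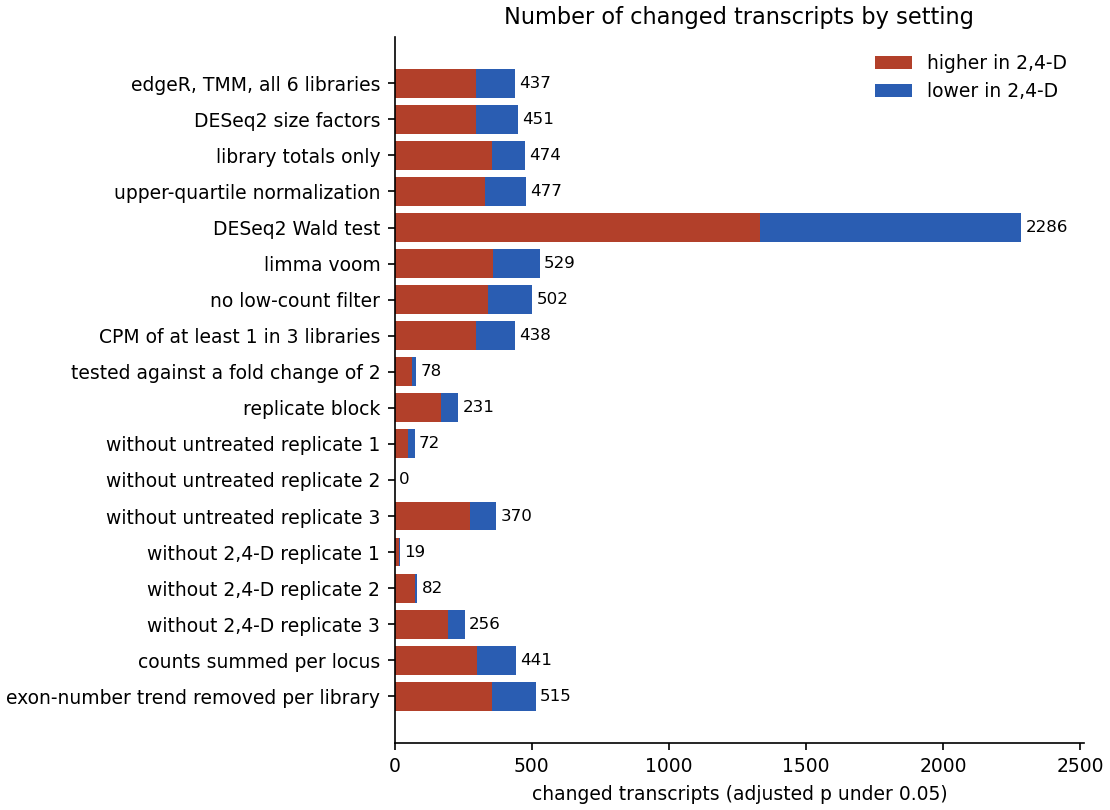
Number of changed transcripts (adjusted p under 0.05), higher in red and lower in blue, with all libraries and under each alternative. The count is 437 with all 6 libraries, 0 without untreated replicate 2, 19 without 2,4-D replicate 1 and 2286 with the DESeq2 Wald test.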

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

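The neighbour, exon and chromosome results were chosen after the data were seen. Against 437 changed transcripts (296 higher, 141 lower), the other scalings, filters and limma voom gave 438 to 529, as did 2 fits added after the data were seen (441 and 515). The DESeq2 Wald test called 2286 (1331 higher, 955 lower), among them all 437; it made 65 false calls in the simulation, and the cause of the excess was not tested. A test against a fold change of 2, which is stricter by construction, called 78 (62 and 16). Deviations of same-numbered libraries from their group means correlated at -0.093, 0.350 and 0.093, and not every library correlated best with its own number. So few correlations cannot tell whether the replicate numbers pair the libraries. With replicate as a block 231 were called (170 and 61), 175 of them shared, and Bradi1g37410.1 was not among them (edgeR adjusted p = 0.0572). Leaving out one library, with fewer samples, gave 0 to 370 changed, 0 to 276 higher and 0 to 94 lower transcripts. The lowest counts came without untreated replicate 2 (0) and without 2,4-D replicate 1 (19). The excess of neighbouring pairs (4.39 times the expected number) stayed past its threshold in each fit with a value, but its size ran from 2.17 times with the DESeq2 Wald test (212 pairs) through 9.09 with the replicate block to 71.9 without 2,4-D replicate 1 (1 pair); none exists without untreated replicate 2. The odds ratio for few exons (2.08) was 3.44 with the replicate block, ranged from 1.61 to 4.46 with one library left out and fell short of the threshold only without untreated replicate 1. The chi-square of lower loci over the chromosomes (14.6, permutation p = 0.00529) passed its threshold in the other scalings, filters and tools and with each region as 1 unit (11.4, p = 0.0213, permutation). With one library left out it ran from 3.56 to 12.7 and missed the threshold without untreated replicate 3, 2,4-D replicate 1 or 2,4-D replicate 3. It also missed it in the test against a fold change of 2 (3.39), with the replicate block (8.59, p = 0.0723, permutation) and with the calls rotated together along the genome (p = 0.426, permutation). The named transcripts kept their direction in all fits, which their choice by no overlap between the groups made all but certain. The real split of the 6 libraries gave 437, 296 and 141, and the highest of the other 9 splits 0 by edgeR (143 to 1412 at an unadjusted p under 0.05), 0 by voom and 148 by DESeq2; only 1 of the 10 splits gave as many, and 10 are too few for a share under 0.05. The planned gene list tests were not run, as no identifier matched the reference. At this depth and spread, simulated changes of 4-fold or less were mostly not recovered by edgeR.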

Other observations

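Only the tests of a stronger response, of abundance deciles and of the odds ratio after removal of the exon trend were laid down before their results were seen; the other tests in this part were chosen after.

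Neighbouring loci changed together more often than random placement gave. Reads shared between similar gene copies might do this. Pairs unlike in exon number or by over 20% in length also exceeded the expected number, by 2.50 times (13 pairs, permutation p = 0.00236). Annotated structure does not show whether 2 loci share sequence, so shared reads stay possible for some of these pairs as well. Reads running on into the next gene would need short gaps, and pairs 5 kb or more apart exceeded expectation by 2.78 times (7 pairs, permutation p = 0.0141). Only 7 of the 24 same-direction pairs lay that far apart, so reads running on stay possible for the nearer ones. The sets were not crossed: some far pairs were alike in structure, and some unlike pairs lay close together. Neither test thus sets aside both explanations at once. Placing calls within abundance deciles left the excess at 4.38 times. For the 11 pairs alike in structure, 41.1 times the expected number, shared reads and common regulation of gene copies cannot be told apart without sequence.

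Transcripts that rose had few exons, and each library also deviated from its replicates along exon number, with Spearman correlations across transcripts from -0.310 to 0.230. The median deviation of each exon class from the mean of all libraries was removed per library. This lowered the odds ratio from 2.08 to 1.505 (95% interval 1.21 to 1.88). The step also removed any shift of a whole exon class between the groups. It therefore cannot tell how much of the pattern such a trend accounts for. After this step higher loci still more often had few exons, with loci treated as independent. Within strata of abundance and length the odds ratio was 2.16. No biological explanation was tested.

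2,4-D replicate 3 stood apart from the other treated libraries. Its depth, 13036151 counts, lay within the range of the others, which argues against depth. A swap with an untreated library would need it to resemble untreated roots, and its mean correlation was higher with treated than with untreated libraries by 0.0735. After removal of exon-class medians the SD of its deviation was 0.825, above the 0.667 of the next library, so an exon trend does not account for it. A stronger response stays open. Among transcripts called without it, it lay beyond both other treated libraries in 39.0% (53.2% of lower and 34.4% of higher ones), but this decides nothing, since those transcripts were chosen on the other libraries and a noisier library would also lie beyond them often.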
